A study of Mus musculus with 2 samples.

How the data were processed

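Chromatin immunoprecipitation followed by sequencing (ChIP-seq) for histone H3 dimethylated at lysine 4 (H3K4me2) was available for 2 biological replicates of mouse neural tube at embryonic day 12.5. Per the labels, the tissue came from the B6NCrl strain, male and female embryos were pooled, 120 embryos went into replicate 1 and 88 into replicate 2, and fragments measured 300 to 500 bp. All samples form 1 group.

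Per the labels and the text deposited with each library, the authors' files are peak lists in narrowPeak format on assembly mm10. Peaks were called on each replicate alone and on both together (the pooled list), and a further list, derived from those 3, holds the replicated peaks. Neither the peak caller nor the rule that makes a peak replicated is given in the sources used here. Each deposited peak carries an enrichment ratio over background that the authors computed, which is not scaled between lists. Each deposited peak also carries a −log10 p and a −log10 q value, which grow with depth. The files hold no read counts, so the depth of each library is unknown and no interval that needs it is given. Signal tracks and alignments were not used here.

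All 38299 replicated peaks had the coordinates of a pooled peak. Of these, 35422 were overlapped, over at least 50% of either peak, by a peak in each replicate's own list, and 2877 were not. No pooled peak that met this condition was missing from the replicated list.

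Genes and 5′ ends came from GENCODE release M21 on GRCm38, and sequence from the GRCm38 assembly, the same build as mm10. No peak ended past a chromosome end in the 21 chromosomes compared. The annotation held 21938 protein-coding gene records on the assembled chromosomes, of which 54 shared a symbol with another record. Coordinates are 1-based on mm10.

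A promoter was the gene record's 5′ end with 1 kb on either side, and it counted as marked when at least 1 bp met a replicated peak. Promoter breadth was the number of bp covered by peaks within 5 kb on either side of the 5′ end. A distal peak lay more than 2.5 kb from every annotated transcript 5′ end, and was counted for a gene when within 50 kb of the gene body. CpG observed/expected was computed over 500 bp on either side of the 5′ end, with classes at 0.6 and 0.4.

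There were 16 gene lists, written from general knowledge of the neural tube and other tissues, and 2 receptor families taken by symbol. One symbol was renamed to that of the annotation (Drgx to Prrxl1) and another (Amy2b) was not found. The lists held 488 gene records, and 8 genes were in more than 1 list. Promoter shares were compared with those of all other protein-coding genes by a two-sided Fisher exact test. Median breadth, over marked members of lists with at least 5 of them, was compared with 10000 random lists of the same size drawn from marked genes. Median counts of distal peaks were compared with 10000 random lists matched on decile of gene length. These permutation tests were two-sided, and the smallest p they can give is 0.0002. Benjamini-Hochberg adjustment was made over the lists of each test, with a threshold of 0.05.

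Overlap and genomic context were set against 100 circular shifts of the peaks along each chromosome. Short recognition words were counted on both strands in distal peaks and in equally long windows 5 kb to the right that met no pooled peak. Each ratio was set beside that of all anagrams of the word. Shares carry exact 95% Clopper-Pearson intervals, which cover counting error only. Values given as mean ± SD are over the 2 replicates' own lists, and genes and peaks were not treated as replicates.

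Named genes followed a fixed rule. In each list these were the 2 marked members of highest enrichment in the replicated list and up to 2 unmarked members in alphabetical order. Over all protein-coding genes they were the 5 with the most bp covered within 5 kb and the 5 with the most distal peaks. Any tie for the former was given as a count, and the 4 Hox clusters were described one by one. The lists, words, tests, this rule and most alternatives were fixed before the data were examined. The alternatives were other overlap rules, windows, reaches, thresholds, peak lists, gene 5′ ends, CpG classes and backgrounds, and each replicate left out in turn. The split of replicated shares by both decile and distance was added after seeing the data. The alternatives that use the 20000 most significant peaks, pooled peaks met in both replicates' own lists, anagrams without CpG, and lists matched on the number of transcript 5′ ends were chosen after seeing the data.

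The interval arithmetic gave the known answer in 6 of 6 checks on simulated data. In 200 simulated lists of 30 genes among 21938, the Fisher exact test called 92% of those drawn with an odds ratio of 5 and 3.5% of lists drawn at random. For breadth, in lists of 30 among 14077 marked genes, 100% of those raised 1.8-fold and 5.5% of those drawn at random were called. For distal peaks, 100% of lists with 3 peaks added per gene and 0% of random lists were called, so this test is conservative at these low counts. All these rates count an unadjusted p under 0.05, whereas the gene lists were called by adjusted p. Tests against lists matched on CpG content or on transcript 5′ ends were not simulated. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.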

Results

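H3K4me2, a histone mark found at promoters and enhancers, was mapped by ChIP-seq in the neural tube of mouse embryos at embryonic day 12.5. There was 1 group of 2 biological replicates, which pooled 120 and 88 embryos of both sexes. The labels define no second condition. The comparisons below are therefore between replicates, between peak lists, between gene lists and other genes, and between parts of the genome. The depth of each library is unknown, since the files give peaks and not reads.

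Replicate 1 held 52982 peaks that covered 54.0 Mb, and replicate 2 held 52079 peaks that covered 58.5 Mb, a mean of 56.2 Mb ± 3.18 (SD, n = 2). Median peak width was 521 bp in replicate 1 and 612 bp in replicate 2. The pooled list held 58260 peaks, and the replicated list, used for the main values, held 38299 peaks that covered 59.1 Mb or 2.17% of the assembled chromosomes. Median width in the replicated list was 1060 bp and median enrichment over background was 7.76.

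The first question was how far the replicates shared peaks. Of the peaks of replicate 1, 74.5% (95% interval 74.2 to 74.9) were met by a peak of replicate 2 over at least 50% of either peak. In the other direction the share was 70.1% (69.7 to 70.5). After circular shifts the shares averaged 3.20% (range 2.85 to 3.62) and 3.18% (range 2.82 to 3.56), so the observed shares were 23.3 and 22.0 times as high. By length, 48.1 Mb was covered in both replicates, which is 89.1% of the bp in replicate 1 and 82.2% of those in replicate 2. Sharing depended on peak strength. By decile of significance, numbered from the lowest, 31.1% of replicate 1 peaks were shared in decile 1, 80.0% in decile 5 and 100% in decile 10.

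Of the pooled peaks, 65.7% (65.4 to 66.1) were in the replicated list. By decile of significance the share was 3.09% in decile 1, 46.8% in decile 4, 99.0% in decile 6 and 100% in each of deciles 7 to 10. Pooled significance and the replicated list come from the same 2 libraries, so this rise is partly built in. Pooled peaks with their midpoint within 1 kb of a transcript 5′ end were replicated in 86.2% of cases, against 55.2% of those farther away. Within deciles that gap was not seen. Near a 5′ end and farther away, the shares were 2.71% and 3.15% in decile 1, 8.95% and 7.54% in decile 2, 19.2% and 18.9% in decile 3, and 44.5% (40.9 to 48.2) and 47.1% (45.7 to 48.5) in decile 4. In decile 5 peaks near a 5′ end had the lower share, 77.7% (74.6 to 80.5) against 82.5% (81.4 to 83.5), and in decile 6 the shares were 98.2% and 99.1%.

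**Figure D1:**
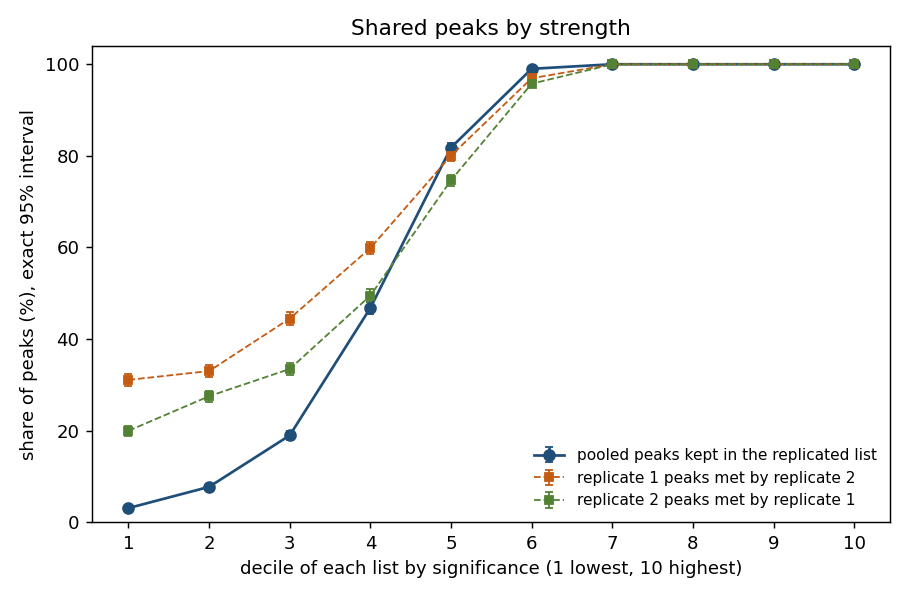
The horizontal axis gives the decile of each list by significance and the vertical axis the share of peaks in percent, with exact 95% intervals. The pooled peaks kept in the replicated list rose from 3.09% in decile 1 to 100% in decile 10, and peaks of either replicate met by the other also reached 100%. The rise for pooled peaks is partly built in, since both lists come from the same libraries.

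Replicated peaks were concentrated at gene starts. Of 38287 on assembled chromosomes, 44.5% (44.0 to 45.0) had their midpoint within 1 kb of a transcript 5′ end, against 6.17% (range 5.72 to 6.74) after shifts, a ratio of 7.22. Exons held 4.87% (shifted 3.29%), introns 29.3% (shifted 39.1%) and the space between genes 21.3% (shifted 51.4%). In the replicates' own lists, 38.1% ± 0.616 (SD, n = 2) lay within 1 kb of a 5′ end, a lower share than in the replicated list. Of the pooled peaks left out of the replicated list, 13.7% had their midpoint there, so that filter itself raises the share. The 17053 peaks within 1 kb had a median width of 1982 bp and a median enrichment of 22.3. The 16095 distal peaks had medians of 671 bp and 3.98.

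Of 21938 protein-coding genes, 14077 had a marked promoter, 64.2% (63.5 to 64.8). In the replicates' own lists the share was 64.6% ± 0.0355 (SD, n = 2), and 98.6% of genes had the same state in both. Across the 14016 genes marked in both, the ranks of promoter enrichment correlated with a Spearman rho of 0.756. This is a relation across genes, which are not independent replicates. CpG content set the share apart. With CpG observed/expected of at least 0.6, 98.6% of 10083 promoters were marked (98.4 to 98.8), between 0.4 and 0.6 86.4% of 3070 (85.1 to 87.6), and under 0.4 16.9% of 8785 (16.1 to 17.7). The odds ratio of the highest against the lowest class was 350.0, with a two-sided Fisher exact p below the smallest number the computation can hold. Marked promoters also differed in enrichment, with medians of 26.5 in the highest class and 14.8 in the lowest.

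The next question was which genes carried the mark. The shares of 6 lists were higher than those of other protein-coding genes, those of 4 were lower, and 8 were not called. All 39 Hox genes were marked (91.0 to 100%; Fisher exact p = 6.03e-08, adjusted 2.71e-07). However, 4 peaks held the 5′ ends of 23 of these genes, so the 39 promoters are not independent, as every test of this list assumes. Of the progenitor patterning factors 34 of 35 were marked, or 97.1% (98.6% ± 2.02, SD, n = 2, in the replicates' own lists; odds ratio 19.0; adjusted Fisher exact p = 1.98e-05). The spinal and hindbrain neuron identity factors were marked in 39 of 41 cases, or 95.1% (96.3% ± 1.72, SD, n = 2; odds ratio 10.9; adjusted Fisher exact p = 1.69e-05). Signalling pathway genes reached 38 of 40 (odds ratio 10.6; adjusted Fisher exact p = 1.98e-05). Pan-neuronal genes and housekeeping genes each reached 29 of 30 (odds ratio 16.2; adjusted Fisher exact p = 1.22e-04).

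Shares were lower for the terminal genes of other tissues, with 3 of 41 marked (7.32%, 1.54 to 19.9; adjusted Fisher exact p = 1.93e-13), and for blood and microglia genes, with 7 of 26 (26.9%, 11.6 to 47.8; adjusted Fisher exact p = 2.37e-04). Olfactory receptors had 2 marked promoters among 1135 and vomeronasal receptors 1 among 329 (adjusted Fisher exact p = 1.42e-145 for the latter). Neurotransmitter and synapse genes and the list of mesenchyme, meninges and pericyte genes both had 25 of 30 marked (adjusted Fisher exact p = 0.0517). Forebrain and midbrain factors had 23 of 28 (adjusted Fisher exact p = 0.0685). Radial glia and early glial genes had 16 of 20, and neural crest, sensory ganglion and Schwann genes 20 of 28. Regulators of other lineages had 27 of 40, endothelial genes 15 of 25 and myelin genes 9 of 14. The adjusted Fisher exact p of these last 5 lists ran from 0.214 to 1.

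Against random lists matched on promoter CpG content the picture changed. The progenitor, neuron identity, signalling and housekeeping lists were then no longer called, nor were the blood and microglia genes lower. For progenitor factors the central 95% of matched lists ran from 88.6 to 100%, so no share could have been called higher. Matched means of 88.9%, 89.3% and 90.7% left little room for neuron identity, signalling and housekeeping genes. Pan-neuronal genes stayed higher, with 96.7% marked against a mean of 76.0% in matched lists (adjusted permutation p = 0.0012), as did Hox genes, with 100% against 89.8% (adjusted permutation p = 0.0187). Neurotransmitter and synapse genes became higher (83.3% against 65.8%; adjusted permutation p = 0.0206), and so did the mesenchyme, meninges and pericyte genes (83.3% against 65.9%; adjusted permutation p = 0.0204). Terminal genes of other tissues stayed lower (7.32% against 27.2%; adjusted permutation p = 0.0018). The neuron identity list was also not called when only the 20000 most significant peaks were used (adjusted Fisher exact p = 0.115), and the differences of the forebrain, neural crest, mesenchyme and myelin lists and of the regulators of other lineages then turned negative with no call.

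**Figure D2:**
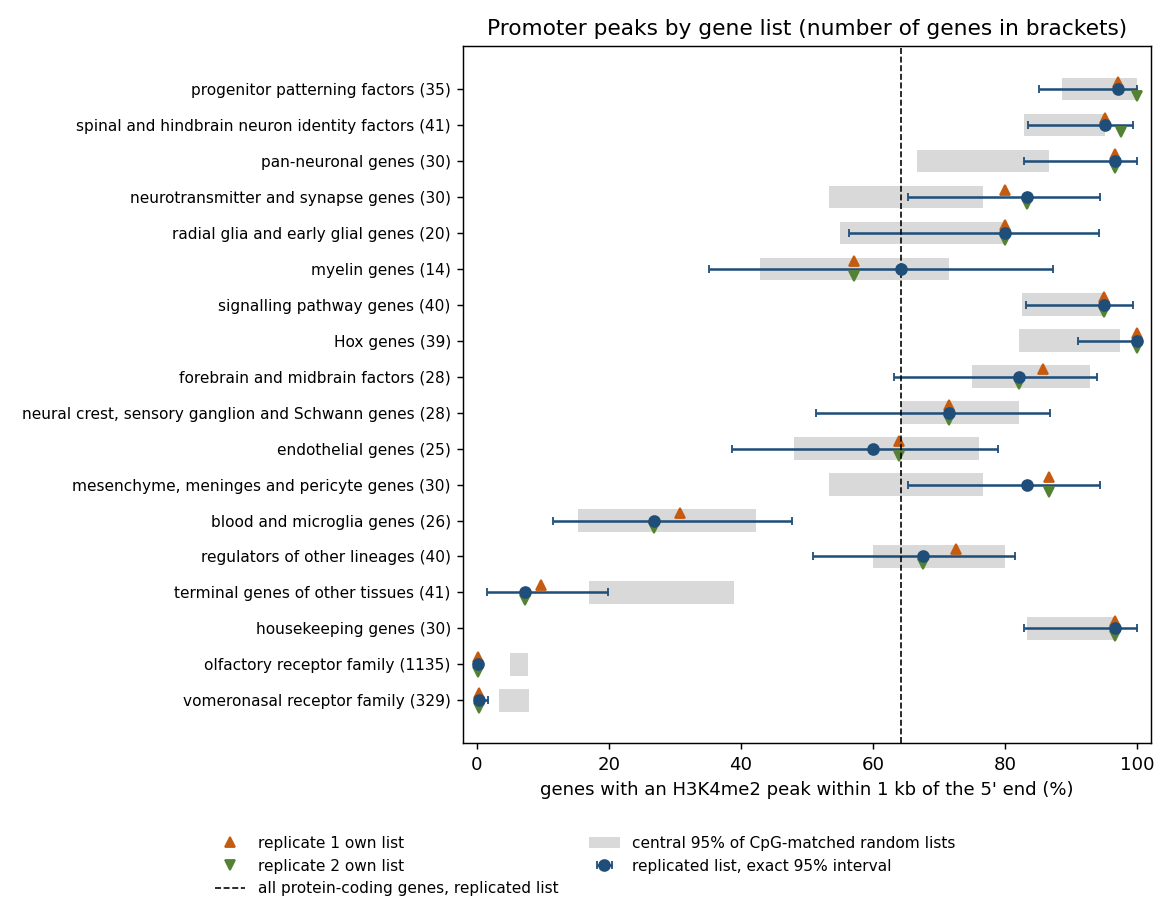
Each row is a gene list, and the horizontal axis is the percent of its genes with a peak within 1 kb of the 5′ end; circles with bars are the replicated list with exact 95% intervals, triangles the replicates' own lists, and grey boxes the central 95% of CpG-matched random lists. Hox, pan-neuronal, synapse and mesenchyme lists lie above their grey boxes, and the terminal genes and both receptor families lie below theirs, with 64.2% of all protein-coding genes as the dashed line.

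Within the lists the highest enrichments at promoters of patterning and neuron identity factors were those of Hes1 (34.9 in the replicated list; 32.4 ± 2.84, SD, n = 2, in the replicates' own lists), Irx5 (34.4), Isl1 (34.5; 32.1 ± 0.441, SD, n = 2) and Foxp1 (33.6). Enrichment is not scaled between lists, so these SDs also hold differences of scale. Rtn1 (34.9) and Syt1 (33.1) led the pan-neuronal genes, and Dlg4 (34.6) and Shank3 (32.7) the neurotransmitter and synapse genes. Sox8 (39.1) led the glial list, followed by Fgfr3 and Sox9 with equal values (36.2), and Cnp (33.7) and Ugt8a (33.5) the myelin list. Etv5 (44.4) and Wnt7b (39.7) led the signalling genes. Dlx2 (38.8) and Pitx3 (30.8) led the forebrain and midbrain factors, and Ret (39.5) and Six4 (38.8) the neural crest list. Kdr (43.7) and Ramp2 (38.9) led the endothelial genes, Acan (35.5) and Kcnj8 (35.4) the mesenchyme list, and Ikzf1 (40.3) and Klf1 (33.7) the blood list. In the remaining lists the leading genes were Nkx3-1 (34.0) and Foxa3 (30.7), Ckm (37.6) and Lor (29.2), and the housekeeping genes Eef2 (40.5) and Ubc (38.6). All these ranks are from the replicated list, and not all held in the replicates' own lists. Ubc had 24.4 in replicate 1's own list, below Atp5b (33.9), and 39.95 in that of replicate 2. Ramp2 had 31.7 in replicate 2's own list, below Fli1 (34.6). For Dlg4, Klf1, Ckm and Lor no replicated peak covered the 5′ end of the gene record. Their nearest peaks lay 399, 36, 283 and 683 bp away, so Lor had no peak within 500 bp. For Klf1, Ckm and Lor no other annotated transcript start was covered either. Whether these peaks belong to neighbouring genes was not tested. The 7 genes from Hoxb3 to Hoxb9 shared 1 peak, with an enrichment of 43.6. Among receptors the marked promoters were those of Olfr658 (11.6), Olfr1033 (6.58) and Vmn1r4 (16.7).

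Several genes without a peak at the 5′ end of the gene record had one at another annotated transcript. This held for Lhx4 (enrichment 27.0), L1cam (15.8), Gabrb3 (33.0), Ddc (3.42), Cyp26b1 (30.4), Rarb (16.3), Egfl7 (24.0), Gata4 (8.68), Fezf2 (5.61), Nkx2-1 (5.17), Aldh1l1 (7.55) and Ywhaz (31.7). Dbx1 had no replicated peak at any annotated 5′ end, but one in replicate 2's own list (2.60) and in the pooled list (1.91). Its nearest replicated peak was 1135 bp away, and 3079 bp were covered within 5 kb (2301 bp ± 721, SD, n = 2). Phox2b, Mag, Mobp, Aqp4, Cdh19, Dbh, Cdh5, Acta2, Col3a1, Aif1, Alas2, Hand1, Acta1 and Adipoq also had no replicated peak there. At the 5′ end of the gene record, Lhx4 (2.07) and Col3a1 (2.497) had a peak in replicate 2's own list and Nkx2-1 (2.86) in that of replicate 1. When any annotated transcript was counted, all 28 forebrain and midbrain factors were marked and their share was called higher.

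Breadth separated the lists further. Marked protein-coding genes had a median of 2775 bp covered within 5 kb of the 5′ end (quartiles 2009 and 3852). Of 15 lists with enough marked genes, 9 were wider than random lists of marked genes and none was narrower; at an unadjusted permutation p under 0.05 none was narrower either. Hox genes had a median of 9942 bp (9848 bp ± 132, SD, n = 2), 3.59 times the random median. Progenitor patterning factors had 6840 bp (6562 bp ± 294, SD, n = 2), a ratio of 2.47. Signalling pathway genes had 5123 bp (ratio 1.85), pan-neuronal genes 4967 bp (1.79), neuron identity factors 4939 bp (1.78) and radial glia and early glial genes 4889 bp (1.76). Each of these 6 lists had a permutation p of 0.0002, the smallest possible, and an adjusted permutation p of 5.00e-04. Neural crest genes (4208 bp; adjusted permutation p = 0.00471), housekeeping genes (3733 bp; 0.0172) and neurotransmitter and synapse genes (3681 bp; 0.0357) were also wider. The synapse call did not hold in the pooled list (ratio 1.28), nor the housekeeping call against lists matched on transcript 5′ ends (adjusted permutation p = 0.06). The housekeeping ratio was then 1.26, against 1.35 in the main test. Forebrain and midbrain factors, with 2751 bp, and regulators of other lineages, with 2699 bp, were not (adjusted permutation p = 0.975 and 0.877). Within 2 kb of the 5′ end, where at most 4001 bp can be covered, 4 lists stayed wider (progenitor, glial, signalling and Hox), and the neuron identity factors had 0.967 times the random median. Regulators of other lineages were then called narrower (0.575; adjusted permutation p = 7.50e-04). They were also called narrower in replicate 1's own list, with a ratio of 0.799, as were blood and microglia genes, with 0.596 (adjusted permutation p = 0.0447 and 0.0237).

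The whole window of 10001 bp was covered at 33 genes, so the 5 widest genes are a tie. Of the 33, 19 were Hox genes. The others included the transcription factor genes Pou3f3, Pax3, Lmx1b, Meis2, Ebf3, Zic1, Lhx1 and Nr2f1, the Notch ligand gene Dll1, the histone demethylase gene Kdm6b and Basp1. The remaining genes, 5730596B20Rik, Gm28308 and Gm28230, start inside the Hoxa and Hoxd clusters. When peaks less than 1 kb apart were joined, 25 stretches of at least 20 kb were found.

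Peaks covered most of each Hox cluster. From the first to the last Hox gene, the replicated peaks covered 94.8% of Hoxa on chromosome 6 (93.9% ± 0.488, SD, n = 2), 91.1% of Hoxc on chromosome 15 (88.7% ± 2.37) and 84.8% of Hoxd on chromosome 2 (81.5% ± 2.09). On chromosome 11 they covered 61.7% of Hoxb (61.1% ± 0.615), whose span includes the gap before Hoxb13. The widest peak of the list, 81143 bp, ran from 102962288 to 103043430 over the 5′ ends of 6 Hoxc genes. A peak of 79513 bp, from 96268012 to 96347524, spanned Hoxb3 to Hoxb9, and one of 73151 bp, from 52155131 to 52228281, spanned Hoxa1 to Hoxa7. The widest Hoxd peak measured 39759 bp and held the 5′ ends of Hoxd3, Hoxd4 and Hoxd8.

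**Figure D3:**
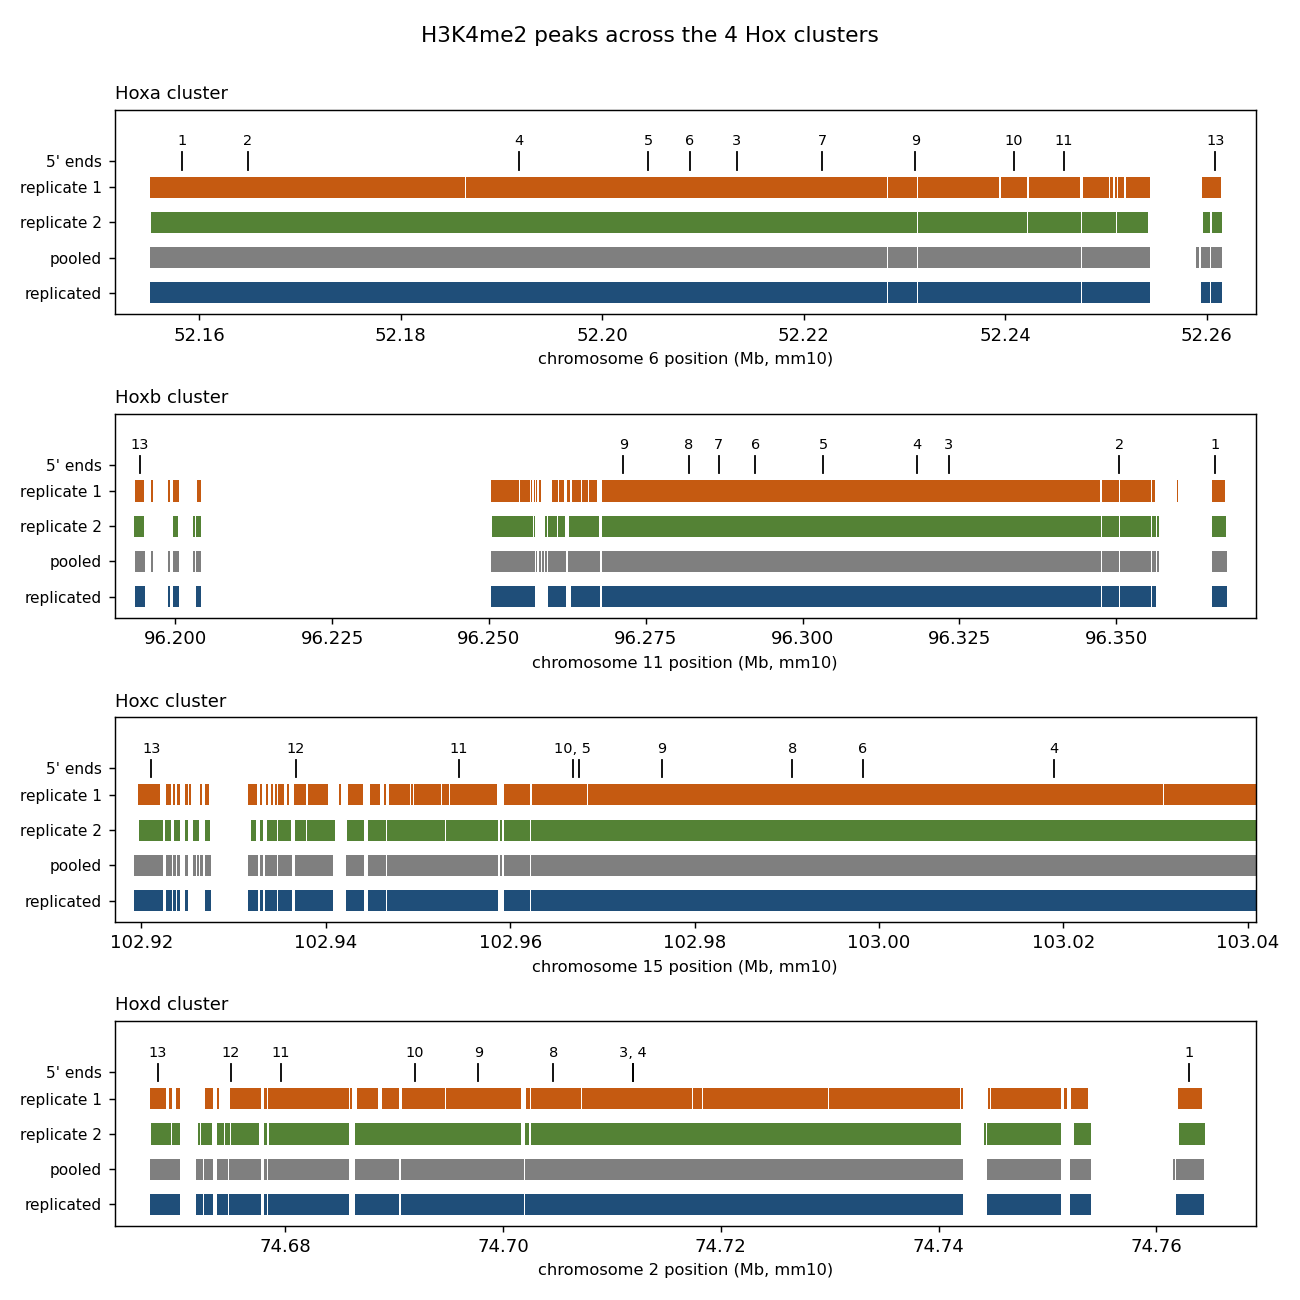
Each panel is a Hox cluster with its position in Mb on the horizontal axis; bars are peaks of the 4 lists and ticks are annotated gene 5′ ends, with numbers for the genes. Peaks of both replicates ran nearly unbroken over Hoxa1 to Hoxa7, Hoxb3 to Hoxb9 and Hoxc4 to Hoxc9, and were split into shorter ones toward genes 11 to 13.

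Distal peaks were counted around the gene bodies. The median protein-coding gene had 0 distal peaks within 50 kb, and the mean was 1.21. Of 18 lists, 8 had a higher median than length-matched random lists. None had a lower one, also at an unadjusted permutation p under 0.05, but a median of 0 in random lists leaves little room for one. Random lists were not matched on the density of transcript 5′ ends around the gene, which sets how much sequence can hold a distal peak. Progenitor patterning factors had a median of 4 against 0 in random lists, and neuron identity factors 3 against 0 (adjusted permutation p = 0.0012 for each). Pan-neuronal genes had 3 against 1 and signalling genes 2 against 0.5 (adjusted permutation p = 0.0036 for each). Hox genes (adjusted permutation p = 0.0012), forebrain and midbrain factors (0.0036), regulators of other lineages (0.0018) and neural crest genes (0.036) each had a median of 2. The Hox call did not hold with a reach of 20 kb or with only peaks of −log10 q of at least 5. Neurotransmitter and synapse genes had 1 against 1, and terminal genes of other tissues 1 against 0 (adjusted permutation p = 1 and 0.556). The genes with the most distal peaks were Gm20388 (153), Gse1 (73), Zfhx3 (48), Fgfr2 (40) and Skap1 (32). The annotated bodies of Gm20388 and Fgfr2 are 4434882 and 2960900 bp long, so their counts include peaks around many other genes.

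Words recognised by transcription factors were counted in 13799 pairs of distal peaks and control windows. The homeodomain word TAATTA had a ratio of 0.975 between peaks and controls, above all 13 of its anagrams (median 0.590, highest 0.883). The E-box word CAGCTG had a ratio of 1.75, at the 51.5th percentile of all its anagrams and at the 92.7th of the 41 anagrams without CpG. The SOX word ACAAAG had a ratio of 1.08 (percentile 75.9), the CRE word TGACGT 1.42 (83.8) and the SP/KLF word GGGCGG 5.25 (80.0 among 5 anagrams). TGACGT itself holds a CpG. None of the 119 anagrams without CpG of TTGGCA, which has the same letters, exceeded 1.27. The percentile of TGACGT therefore cannot be told apart from an effect of CpG. The words CAGATG, TTGGCA, GTTGCC, TGAGTCA and AGATAA had ratios of 1.00, 1.03, 1.30, 0.871 and 0.764, at percentiles from 31.5 to 56.4 of all anagrams. Of the anagrams without CpG, a set chosen after seeing the data, ACAAAG lay at the 91.7th percentile, TTGGCA at 80.7, GTTGCC at 77.1, CAGATG at 69.7 and TGAGTCA at 63.3. GTTGCC thereby went from 0.679 to 1.14 times the anagram median. No p-value was taken from anagrams.

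Chromosome X carried fewer peaks than any autosome. Both pools held male embryos, which have fewer copies of X than of each autosome, and no correction was made for this. Copy number and other causes were therefore not told apart. Of the pooled peaks on X 82.7% were replicated, against 63.0 to 70.4% on autosomes. The density on X was 5.68 replicated peaks per Mb, against 11.2 to 25.8 on autosomes (median 15.4). In the replicates' own lists it was 6.86 per Mb ± 0.0606 (SD, n = 2). Per protein-coding gene, X had 0.979 peaks and the autosomes 1.23 to 2.29. The share of marked promoters on X was 49.3%, against 52.7 to 77.3% on autosomes, and 49.7% against 57.3 to 77.3% with the receptor families left out.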

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

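The tests of CpG content and of other tissues, and both tests on mesenchyme genes, were chosen after the results were seen, as was the match on transcript 5′ ends. Replicates left out in turn and CpG-matched lists were planned as alternatives.

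Peaks lay in data outside the main measurements, and they are given because their number was not 0; no noise level was available to compare them with. There were 12 replicated peaks on scaffolds that are not assembled into chromosomes and 7 on chromosome Y. Peaks on Y were expected, since both pools held male embryos, and 4 of them lay within 1 kb of the 5′ ends of Kdm5d, Eif2s3y, Uty and Ddx3y. The pooled list held 19961 peaks that are not in the replicated list. Their median enrichment was 2.40 and their median width 246 bp, 13.7% had their midpoint within 1 kb of a transcript 5′ end, and 4348 had a −log10 q under 2.

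Promoters of 27 of 40 regulators of other lineages were marked. Some of these genes, Foxa1 among them, are also known from the neural tube, so not all of these peaks are unexpected. The share differed from that of CpG-matched random lists by -2.98 percentage points, inside the central 95% of 60.0 to 80.0%, so CpG content may account for it. Whether cells of other tissues contributed stays open. Terminal genes of other tissues were marked less often than in CpG-matched lists, by a difference of -19.9 percentage points, but many of them are used only in mature tissue, and the mesenchyme genes were marked more often than in theirs. No biological explanation was tested, since the design has 1 group.

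Coverage around the 5′ end was wider than in random lists for 9 gene lists. With CpG-matched random lists 100% of the 9 kept the call, so CpG content within 500 bp of the 5′ end is not the whole cause. CpG content in the rest of the window was not matched, so its part stays open. With random lists matched on the number of transcript 5′ ends 88.9% kept it, and the exception was the housekeeping list (adjusted permutation p = 0.06). Its ratio to the random median was then 1.26, against 1.35 in the main test. In both replicates' own lists, which were called without pooling, 100% kept it, so the calls did not need the pooled list. Breadth counts covered bp, and joining peaks adds only the gaps between them. A loss of calls was therefore unlikely from the start, and the test says little about joining. No biological explanation was tested in this design. The Hox result also rests on neighbouring genes that share peaks.

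Promoters of 25 of 30 mesenchyme, meninges and pericyte genes were marked. The share of marked members was 17.4 percentage points above the mean of CpG-matched lists and above their central 95% (53.3 to 76.7%). CpG content within 500 bp of the 5′ end is thus not the whole cause. In a further test 6 members assumed to be used by the neural tube itself were left out (Zic2, Sox5, Crabp2, Col2a1, Pax9 and Foxd1). Of the other 24, 79.2% were marked, above the central 95% of matched lists (45.8 to 70.8%). Mesenchymal cells in the dissected material are a candidate source. Col1a1 and Col1a2 had enrichments of 14.8 and 22.7. Col3a1 and Acta2 had no replicated promoter peak, and Col3a1 only a weak one in replicate 2's own list (2.497). In an unplanned comparison 8 of 13 members with CpG observed/expected under 0.4 were marked, against 16.8% of other such promoters (adjusted Fisher exact p = 0.00124). Neurotransmitter and synapse genes had the same counts, so this does not single out mesenchymal cells. Use of the other genes within the neural tube stays open too. Endothelial genes and blood and microglia genes differed from CpG-matched lists by -2.46 and -1.63 percentage points, with no call. Apart from those 6 members, no biological explanation was tested, since the design has 1 group.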

How the results depend on the processing

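The alternatives that use the 20000 most significant peaks, overlap with both replicates' own lists, anagrams without CpG and random lists matched on transcript 5′ ends were chosen after seeing the data. No paired analysis was possible because there is 1 group. The 50000 most significant peaks were not run for the replicated list, which holds 38299. The cause of the changes below was not tested, except where the alternative's construction states it. Unknown depth limits what can be said of weak peaks.

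The share of replicate 1 peaks met by replicate 2, and of the reverse, was 78.5% and 73.8% with 1 bp of overlap, 58.2% and 59.2% with 50% of both peaks, 79.8% and 72.9% with −log10 q of at least 2, and 76.6% and 71.0% with the 50000 most significant peaks. Counting pooled peaks that a peak of each replicate's own list met, in place of the authors' replicated list, gave 60.8%. Matching that list to the pooled one by overlap was void, since its peaks have pooled coordinates. The rank relation at promoters gave a rho of 0.901 by significance value and 0.747 in 500 bp windows. The share of protein-coding genes marked was 63.3% with 500 bp windows, 65.5% with 2 kb, 65.2% in the pooled list, 63.9% at −log10 q of at least 5, 67.6% with any annotated transcript, 61.4% with the 20000 most significant peaks, and 64.5 to 64.6% without each replicate.

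For promoter shares of gene lists, 144 of 180 values from 10 settings kept their direction and their side of the threshold, given here as percentage points above other genes. The pan-neuronal, Hox, radial glia, terminal and both receptor lists did so under every setting. Against CpG-matched lists the calls were lost for progenitor factors (2.30), neuron identity factors (6.24), signalling (5.74), housekeeping (5.92) and blood genes (-1.63). Calls were gained for synapse (17.5) and mesenchyme genes (17.4). For progenitor factors no share could have been called higher, since the central 95% of CpG-matched lists reached 100%. There the differences of forebrain factors (-3.07), neural crest genes (-2.91) and regulators of other lineages (-2.98) reversed with no call. With the 20000 most significant peaks neuron identity factors lost their call (14.3), and forebrain factors (-0.669), neural crest (-0.669), mesenchyme (-4.72), regulators (-13.9) and myelin genes (-11.4) reversed with no call.

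Calls were gained for synapse genes with 500 bp windows (20.1) and any transcript (25.7). Forebrain factors gained one with 2 kb windows (23.9) and any transcript (32.4); without each replicate the difference was 17.6 to 21.2, called without replicate 2. Mesenchyme genes gained one with 2 kb windows (21.2), the pooled list (24.8) and any transcript (19.0), and without each replicate (22.1 to 22.2). Myelin genes, never called, reversed to -6.13 with 500 bp and -1.17 with 2 kb windows, -0.908 in the pooled list, -6.76 at −log10 q of at least 5, -3.37 with any transcript and -7.45 to -7.40 without each replicate. Endothelial genes, never called, reversed to 2.55 with 2 kb windows, 2.81 in the pooled list and 8.36 with any transcript.

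For breadth, 83 of 105 values from 7 settings kept direction and side, given here as ratios to the random median. The progenitor, glial, signalling and Hox lists stayed wider under every setting. With 2 kb windows, which hold at most 4001 bp, 4 lists were wider. Pan-neuronal (1.07), synapse (1.01), neural crest (1.11) and housekeeping genes (1.11) lost their calls, neuron identity factors reversed with no call (0.967), and regulators of other lineages became narrower (0.575). Synapse genes were not called in the pooled list (1.28), nor housekeeping genes with lists matched on transcript 5′ ends (1.26). Mesenchyme genes were wider than CpG-matched lists (1.34). Reversals with no call were forebrain factors with 10 kb windows (1.23), CpG-matched lists (1.08) and lists matched on 5′ ends (1.04), endothelial genes with 10 kb (1.09), the pooled list (1.00), CpG-matched lists (1.05) and matched 5′ ends (1.04), and regulators with CpG-matched lists (1.10) and matched 5′ ends (1.02). Without each replicate the ratios were 0.891 to 1.02 for forebrain factors and 0.974 to 1.22 for mesenchyme genes. They were 0.596 to 0.689 for blood genes and 0.799 to 0.807 for regulators, both called narrower without replicate 2.

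For distal peaks, 91 of 108 values from 6 settings kept direction and side, given here as percentiles among random lists. Hox genes lost their call with a reach of 20 kb (49.985) and at −log10 q of at least 5 (97.2). Calls were gained for glial genes at 100 kb (99.5) and in the pooled list (99.8), for endothelial genes at 100 kb (99.9) and at −log10 q of at least 5 (99.8), for mesenchyme genes in the pooled list (99.98), and at 100 kb, as fewer peaks, for the olfactory (0.015) and vomeronasal (0.01) families. Without each replicate the percentiles were 91.3 to 99.5 for endothelial and 96.7 to 99.8 for mesenchyme genes, both called without replicate 2, and 33.0 to 84.0 for synapse genes, never called. Reversals with no call were blood genes at 20 kb (48.5), at 100 kb (42.6) and at −log10 q of at least 5 (31.8), myelin genes at 20 kb (42.7) and terminal genes at −log10 q of at least 5 (44.7).

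Shares of peaks near a 5′ end, in exons, in introns and between genes moved to 33.6, 7.13, 36.8 and 22.4% with a distance of 500 bp, to 56.0, 2.88, 21.6 and 19.5% with 2.5 kb, and to 34.0, 5.62, 37.2 and 23.2% in the pooled list. Without each replicate they were 37.7 to 38.5%, 5.43 to 5.55%, 34.6 to 34.9% and 21.3 to 22.0%. The difference between CpG classes was called under each of 4 settings. Density on X, as a percent of the autosome median, was 36.8 in the replicated list, 28.8 in the pooled list and 30.8 to 32.0 without each replicate.

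Ratios of words over their anagram median moved with the central 500 bp for CAGCTG (1.07), CAGATG (1.02), ACAAAG (1.15), TAATTA (1.76) and AGATAA (1.05). With anagrams without CpG they moved for CAGCTG (1.63), CAGATG (1.08), TTGGCA (1.13), GTTGCC (1.14) and TGAGTCA (1.06). Of 612 enrichment values of named genes under 6 settings, 495 stayed within the spread between replicates. That spread is the SD of values not scaled between lists, so it mixes differences of scale with those between replicates. Genes without a peak under any setting count as unchanged by construction.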

Other observations

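The genes named here were chosen after their values were seen. All 3 loci of the microRNA miR-9 lay in the 10 longest stretches of peaks. Mir9-2 lay in a stretch of 29764 bp on chromosome 13, Mir9-1 in one of 29313 bp on chromosome 3 and Mir9-3 in one of 25923 bp on chromosome 7. After the 4 Hox clusters, the longest stretch was the 31466 bp around Pou3f3 and Pantr1 on chromosome 1. Further stretches of over 20 kb held the 5′ ends of Nr2f2, Ebf3, Meis2, Zic1, Ptch1, Pax6, Pou3f2, Lhx1, Skor1, Pax2 and Sox2. The remaining ones held those of Nr2f1, Bahcc1, Skida1 with Mllt10, and Tshz1 with Zadh2. Zic4 and Aatf shared the stretches of Zic1 and Lhx1. A stretch on each of chromosomes 8 and 2 held no 5′ end of a protein-coding, long intergenic noncoding RNA or microRNA gene.

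Among clustered protocadherins, of the alpha genes named with a number, 0 of 12 had a marked promoter in the replicated list and 1 in that of replicate 2, although their median CpG observed/expected was 0.684. The gamma A genes had 10 of 12 marked and the gamma B genes 1 of 6, against 2 of 6 in each replicate's own list. The beta genes had 1 of 22. No difference between these groups was tested. How far near-identical copies lowered the number of placed reads was not tested.

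Other gene types carried the mark at very different rates. Of genes annotated as long noncoding RNAs from bidirectional promoters, 94.2% of 190 were marked (89.9 to 97.1). The shares were 39.3% of 2959 antisense genes, 19.5% of 5854 long intergenic noncoding RNAs, 17.5% of 2202 microRNA genes and 2.90% of 9940 processed pseudogenes. None of the 218 immunoglobulin variable genes was marked, which allows a share of up to 1.68% by the exact interval.

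The highest CpG class held 140 unmarked promoters. Otx2 was among them, with CpG observed/expected of 0.770 and the nearest replicated peak 8655 bp from the 5′ end of its gene record, though a further annotated transcript start of Otx2 had a peak with an enrichment of 2.76.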
